A study of Homo sapiens with 42 samples.

How the data were processed

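Gene expression was measured on Affymetrix human transcriptome arrays in CD8 T cells and CD68 monocytes sorted from blood of pediatric patients with hemophagocytic lymphohistiocytosis (HLH) or severe sepsis. Per the labels, total RNA was isolated with the Arcturus PicoPure kit, amplified with the Ovation Pico WTA system and labelled with biotin. Per the submitters' processing notes, the arrays were processed by RMA in Affymetrix Expression Console, for which no version is given. The deposited values are log2 signals, 1 value for each of 70523 probe sets on each of 42 arrays, from 2.35 to 19.93. The brightest probe sets sit at the upper end of this scale, a ceiling. Array means lay between 5.21 and 5.30, medians between 4.22 and 4.66 and SDs between 2.05 and 2.64, so the deposited arrays did not share 1 distribution. Differences are given on this deposited log2 scale and are not calibrated fold changes. The number of arrays limits the precision.

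The groups were HLH CD8 (n = 12), sepsis CD8 (n = 10), HLH CD68 (n = 12) and sepsis CD68 (n = 8). The replicate number in the array titles is the patient number, and 19 patients (11 with HLH and 8 with sepsis) gave both populations. For the arrays of the same patient, the correlation of the deviations from the group means had a median of 0.108 (-0.105 to 0.303), against -0.0060 for different patients of the same disease. A check for mixed-up samples found 0 of 19 patients whose arrays differed. The check compared a yes or no call per array, so it cannot detect a swap between patients with the same call. 1 CD68 array titled sepsis, replicate 14, carries HLH in its disease field. It was analysed as sepsis, as its title, the stated group sizes and the CD8 array of the same number have it, and alternatives left it out or counted it as HLH. The labels give no batch, date or treatment.

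Of the probe sets, 23781 carried 1 gene symbol, 1543 several and 45199 none, and 88 probe sets of XIST, TSIX or Y-linked genes were left out, which left 22401 genes. A probe set was kept where it exceeded the median of all probe sets of its array on at least 10 arrays for CD8 and 8 arrays for CD68 and for the fits of all 4 groups. Each gene was represented by its probe set with the highest mean. Chromosomes served only to leave out Y-linked genes and, among probe sets without a single gene symbol, those with X or Y identifiers. Positions within chromosomes were not used here.

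Each disease comparison was fitted within its population with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8), two-sided, at a Benjamini-Hochberg adjusted p of 0.05. A fit of all 42 arrays gave the difference between the disease effects of the populations (HLH minus sepsis in CD68 minus HLH minus sepsis in CD8) and the CD68 minus CD8 difference. The tests were tried on simulated data in which 200 genes were shifted. At a log2 shift of 1 and of 2, limma recovered 72.5% and 93% of them in CD8, 65.5% and 90.5% in CD68, 51% and 85.5% for the difference of the disease effects, and 86% and 99.5% for CD68 minus CD8. In a separate simulation of the CD8 arrays, with the cell cycle list shifted by 1, camera called that list and no other. The simulated genes varied independently of each other, whereas the estimated correlation of this list in the real CD8 arrays was 0.80. Camera was therefore not tried on correlated genes.

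29 gene lists were fixed before the data were examined: IFN-gamma response, type I IFN response, MHC class II presentation, MHC class I and immunoproteasome, cell cycle, cytotoxic effector, T cell activation and checkpoint, naive and memory T cell, familial HLH and granule exocytosis genes, scavenger and haem handling, inflammatory cytokines and NF-kappaB, sepsis monocyte alarmin, glucocorticoid response, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, immediate early and heat shock, unfolded protein response, and markers of T cells, CD4 and regulatory T cells, gamma-delta T cells, NK cells, B cells, plasma cells, monocytes, neutrophils and granule precursors, dendritic cells, erythroid cells and platelets. Lists with at least 5 tested members were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation, and by fry. A list mean per array was the mean over the list's tested genes of the log2 value minus the gene's mean over the arrays of its population. List means were compared by two-sided permutation tests, exact (125970 splits) for CD68 and with 100000 resamples for CD8. Relations between the list means of a patient's arrays were given as Pearson's r and Spearman's rho with permutation p values, exact in sepsis, adjusted over 4 relations.

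The genes named in each disease comparison were fixed by rule before the data were examined: the 10 largest differences in each direction past the threshold (or, where none passed, the 5 smallest p in each direction), leaving out uncharacterised loci, noncoding RNA and antisense symbols, plus up to 4 members with the smallest p of each reported list, plus IFNG, PRF1, CXCL9, CXCL10, CD163 and HLA-DRA. For the difference of the disease effects the 5 largest in each direction were named, and for CD68 minus CD8 7 marker genes and the 3 largest in each direction. Members that make up a count of 5 or fewer are named where they fall outside this rule, after their values were seen.

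The alternatives were no low-signal filter, a filter at the 75th percentile, the mean of a gene's probe sets, a second quantile normalization, centring of the arrays, trend and robust eBayes, array weights, 1 fit of all 42 arrays without and with the patient as a replicate block, the marker list mean of the other sort as a covariate, the conflicting array left out or counted as HLH, a log2 difference of at least 1, and list medians in place of means. After the data were seen, these were added: leaving out arrays with an array weight under 0.6, a covariate made of probe sets of keratin-associated, late cornified envelope, SPRR and olfactory receptor genes, the SD of the array as a covariate, and permutation tests of all list means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.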

Results

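Messenger RNA was profiled in CD8 T cells and CD68 monocytes sorted from the blood of children with HLH, a syndrome of overactive lymphocytes and macrophages, or with severe sepsis. The 42 arrays made 4 groups: HLH CD8 (n = 12), sepsis CD8 (n = 10), HLH CD68 (n = 12) and sepsis CD68 (n = 8). Both populations came from 19 of the patients. The study's title asks whether an IFN-gamma signature separates HLH from sepsis, and the comparisons below address this within each sorted population.

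ITGA6, a laminin-binding integrin chain, was lower in CD8 T cells of HLH than of sepsis, at 8.44 ± 1.64 (SD, n = 12) against 11.22 ± 0.70 (SD, n = 10) on the log2 scale, a difference of -2.78 (SE 0.54, limma adjusted p = 0.00882). CD248, a glycoprotein of naive CD8 T cells, differed by -2.75 (SE 0.56), SLAMF6, a lymphocyte receptor, by -2.37 (SE 0.61), and THEMIS, a regulator of T cell receptor signalling, by -1.78 (SE 0.34). STX11, a syntaxin needed for cytotoxic granule release and mutated in a familial form of HLH, was higher by 1.15 (SE 0.21, adjusted p = 0.00502). GBP2, an interferon-inducible GTPase, was higher by 1.36 (SE 0.35, adjusted p = 0.0393). STX11 was at 5.70 ± 0.61 (SD) in HLH, with 12 of 12 arrays above the sepsis median, and at 4.55 ± 0.29 (SD) in sepsis.

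In total 346 of 12814 genes passed the threshold in CD8 cells, 166 higher and 180 lower in HLH, and 81 of them (23 higher and 58 lower) differed by at least 1 on the log2 scale. The balance of higher and lower genes depended on the processing, at 256 and 190 after a second quantile normalization, 254 and 178 without the filter, 42 and 81 with the filter at the 75th percentile and 178 and 276 in 1 fit of all arrays. It was 429 and 228 with the skin and olfactory families as a covariate. At an unadjusted p under 0.05 there were 2291 genes, where chance gives 640.7. The other large differences among lower genes were DNAJB1, a heat shock co-chaperone (-2.20, SE 0.43), FOSB, an AP-1 transcription factor (-2.03, SE 0.49), RASGEF1B (-1.93, SE 0.36), the kinase SIK1 (-1.91, SE 0.49), SNAPC1 (-1.91, SE 0.31) and RAPGEF6 (-1.78, SE 0.39). Among higher genes they were the immunoglobulin lambda variable genes IGLV5-48 (1.6, SE 0.20), IGLV4-60 (1.35, SE 0.19), IGLV5-37 (1.28, SE 0.17) and IGLV11-55 (1.28, SE 0.21). They also included the heavy chain variable genes IGHV2-5 (1.07, SE 0.20) and IGHV2-70 (0.99, SE 0.17), the nuclear envelope protein gene SYNE2 (1.54, SE 0.41) and the chaperone gene DNAJB11 (1.44, SE 0.33). Of these named genes, alternatives ended the calls of SYNE2 (4 of 11), DNAJB11 and GBP2 (3 of 11 each), STX11 (2 of 10), SLAMF6 and SIK1 (2 of 11 each), FOSB and RAPGEF6 (1 of 11 each) and IGHV2-70 (1 of 10). IGLV5-48 averaged 6.31 ± 0.43 (SD) in HLH and 4.72 ± 0.54 (SD) in sepsis. The count fell to 123 with a filter at the 75th percentile of each array and to 131 with the monocyte marker list mean of the CD8 array as a covariate. It rose to 657 with the skin and olfactory families and to 580 with the array SD as covariates.

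Several effector genes had large differences that did not pass. GZMB, a cytotoxic granule protease, was at 11.36 ± 3.40 (SD) in HLH and 7.27 ± 2.09 (SD) in sepsis, a difference of 4.09 (SE 1.19, adjusted p = 0.0671) with 11 of 12 HLH arrays above the sepsis median. IFNG, which encodes the cytokine itself, was at 9.91 ± 4.05 (SD) and 6.64 ± 2.26 (SD), a difference of 3.27 (SE 1.38, adjusted p = 0.212). PRF1, the pore-forming granule protein gene, differed by 2.20 (SE 0.94, adjusted p = 0.215) and HLA-DRA, an MHC class II chain gene, by 3.01 (SE 1.12, adjusted p = 0.153), or 1.82 with the monocyte marker list mean as a covariate. CD163, a macrophage scavenger receptor gene, differed by 0.07 (SE 0.12, adjusted p = 0.785). CXCL9 and CXCL10, chemokine genes induced by IFN-gamma, were below the low-signal filter in CD8 cells, at means of 3.96 and 4.56 in HLH.

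Camera called 12 of the 25 lists tested in CD8 cells, 7 higher and 5 lower in HLH. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.573. Fry called 1 list, and the permutation tests of the list means called 2, the immediate early and heat shock list and the glucocorticoid response list.

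Of the 7 higher lists, the cell cycle list had the smallest p (adjusted p = 1.28e-07, and adjusted p = 0.632 with an estimated correlation). All 33 of its tested genes were higher, with a median of 0.58, and none passed singly, whether adjusted over all genes or adjusted over the list alone. The cell cycle list mean was 0.30 ± 1.02 (SD, n = 12) in HLH and -0.35 ± 0.30 (SD, n = 10) in sepsis (permutation adjusted p = 0.205). Only 7 of 12 HLH arrays lay above the sepsis median. MKI67, the proliferation marker, differed by 2.10 (SE 0.77), NUSAP1 by 1.72 (SE 0.72), CENPF by 1.24 (SE 0.46) and CENPE by 0.94 (SE 0.39), the last 3 being mitotic spindle genes. For the cytotoxic effector list 19 of 24 genes were higher, with a median of 0.98 (adjusted p = 0.00995, and 0.632 as adjusted p with an estimated correlation). Its genes GZMB and FASLG, the Fas ligand gene (1.10, SE 0.34), passed when adjusted over the list alone, and CCL3 differed by 2.78 (SE 1.01). For the IFN-gamma response list 20 of 23 genes were higher, with a median of 0.30 (adjusted p = 4.49e-04, and adjusted p = 0.632 with an estimated correlation). GBP2 and APOL6 (0.73, SE 0.20) passed the threshold, the call of APOL6 ended under 8 of 11 alternatives, 3 genes passed adjusted over the list alone, SERPING1 differed by 0.38 (SE 0.11) and WARS1 by 1.12 (SE 0.40). The list of familial HLH and granule exocytosis genes had 10 of 17 genes higher, median 0.16 (adjusted p = 0.0350, and adjusted p = 0.632 with an estimated correlation). STX11 alone passed, VAMP7 differed by 0.40 (SE 0.19) and SH2D1A by 0.94 (SE 0.46).

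The MHC class II presentation list had 15 of 16 genes higher, median 0.27 (adjusted p = 0.0339, and adjusted p = 0.632 with an estimated correlation). Members included HLA-DOA at -0.52 (SE 0.15), CIITA at 0.30 (SE 0.11) and CD74 at 1.43 (SE 0.69). HLA-DOA was the only member past the threshold adjusted over the list alone. The T cell activation and checkpoint list had 14 of 17 genes higher, median 0.14 (adjusted p = 0.0489, and adjusted p = 0.632 with an estimated correlation). CXCR6 (0.72, SE 0.20) passed adjusted over the list alone, HAVCR2 differed by 1.31 (SE 0.48), LAG3 by 1.15 (SE 0.46) and CD69 by -1.98 (SE 0.80). The monocyte marker list was also higher, in 19 of 19 genes, median 0.33 (adjusted p = 2.20e-05, and adjusted p = 0.632 with an estimated correlation). CD300E passed the threshold at 0.21 (SE 0.06), a call that 4 of 9 alternatives ended, with means of 4.42 and 4.21 near the array medians. LYZ, the lysozyme gene, differed by 2.77 (SE 1.22), MS4A6A by 0.37 (SE 0.15) and MS4A7 by 0.20 (SE 0.08). With the monocyte marker list mean of the same array as a covariate, 1 of these 7 calls stayed, that of the cell cycle list (median 0.53, adjusted p = 1.60e-04), and the 5 lower lists below kept theirs. The medians of the others were then 0.23 for the IFN-gamma response (adjusted p = 0.232), 0.11 for MHC class II (adjusted p = 0.786), 1.0 for cytotoxic effector genes (adjusted p = 0.197), 0.13 for T cell activation (adjusted p = 0.368) and 0.13 for familial HLH genes (adjusted p = 0.131). The monocyte marker list, from which the covariate was made, had a median of -0.016 (adjusted p = 0.944). With this covariate the differences were 0.61 for WARS1, 0.23 for SERPING1, 0.73 for CD74 and 0.18 for LYZ.

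Of the 5 lower lists in CD8 cells, the immediate early and heat shock list, transcripts that respond within minutes to stimulation or stress, had 19 of 25 genes lower, median -0.71 (adjusted p = 1.30e-05, and adjusted p = 0.613 with an estimated correlation). DNAJB1, FOSB, DNAJA1 (-0.91, SE 0.25), NR4A1 (-0.71, SE 0.17) and EGR3 (-0.50, SE 0.09) fell, with the call of NR4A1 ended under 2 of 11 and that of EGR3 under 2 of 10 alternatives. In the same list 12 genes were lower and 1 higher when adjusted over the list alone. The naive and memory T cell list had 18 of 18 genes lower, median -0.85 (adjusted p = 5.55e-06, and adjusted p = 0.613 with an estimated correlation), with 4 past the threshold adjusted over the list alone. SATB1, a chromatin organiser, differed by -1.20 (SE 0.33), LEF1, a transcription factor of naive T cells, by -1.58 (SE 0.51), LRRN3 by -1.10 (SE 0.37) and ACTN1 by -0.80 (SE 0.29). The glucocorticoid response list had 12 of 14 genes lower, median -0.46 (adjusted p = 9.58e-04, and adjusted p = 0.573 with an estimated correlation). KLF9 passed the threshold at a difference of -1.0 (SE 0.27), a call that 9 of 11 alternatives ended, 5 genes passed adjusted over the list alone, SGK1 differed by -1.08 (SE 0.33), IRS2 by -1.34 (SE 0.45) and ERRFI1 by -0.43 (SE 0.13). The T cell marker list had 14 of 16 genes lower, median -0.21 (adjusted p = 0.0293, and adjusted p = 0.632 with an estimated correlation). THEMIS fell, 4 genes passed adjusted over the list alone, CD3E differed by -1.25 (SE 0.35), BCL11B by -1.37 (SE 0.46) and CD3G by -1.37 (SE 0.48). Cytosolic ribosomal protein genes were lower in 19 of 24, median -0.19 (adjusted p = 0.00193, and adjusted p = 0.632 with an estimated correlation). Members included RPL34 (-0.43, SE 0.13), RPL10A (-0.58, SE 0.21), RPL19 (-0.59, SE 0.25) and RPS14 (-0.52, SE 0.24).

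The other 13 lists tested in CD8 cells were not called. Their medians were 0.11 for the type I IFN response (adjusted p = 0.0575), 0.16 for MHC class I and immunoproteasome (adjusted p = 0.131), 0.11 for oxidative phosphorylation (adjusted p = 0.131), -0.09 for glycolysis and hypoxia (adjusted p = 0.149) and 0.04 for the unfolded protein response (adjusted p = 0.860). In the MHC class I list, TAPBP, a peptide-loading chaperone, rose by 0.67. Medians of the inflammatory cytokine, sepsis monocyte alarmin and scavenger lists were 0.13 (adjusted p = 0.198), 0.12 (adjusted p = 0.210) and 0.04 (adjusted p = 0.591). For markers of other cells they were 0.24 for NK cells (adjusted p = 0.198), 0.10 for neutrophils (adjusted p = 0.131), 0.05 for dendritic cells (adjusted p = 0.484), 0.03 for erythroid cells (adjusted p = 0.828) and 0.08 for platelets (adjusted p = 0.341). The scavenger and erythroid lists had a median above 0 and a mean below 0, and camera's direction for the unfolded protein response and erythroid lists was down. Too few genes passed the filter to test markers of CD4 and regulatory T cells (4 genes, median 0.34), gamma-delta T cells (1 gene, -0.53), B cells (4 genes, median -0.04) and plasma cells (3 genes, median 0.14).

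**Figure D1:**
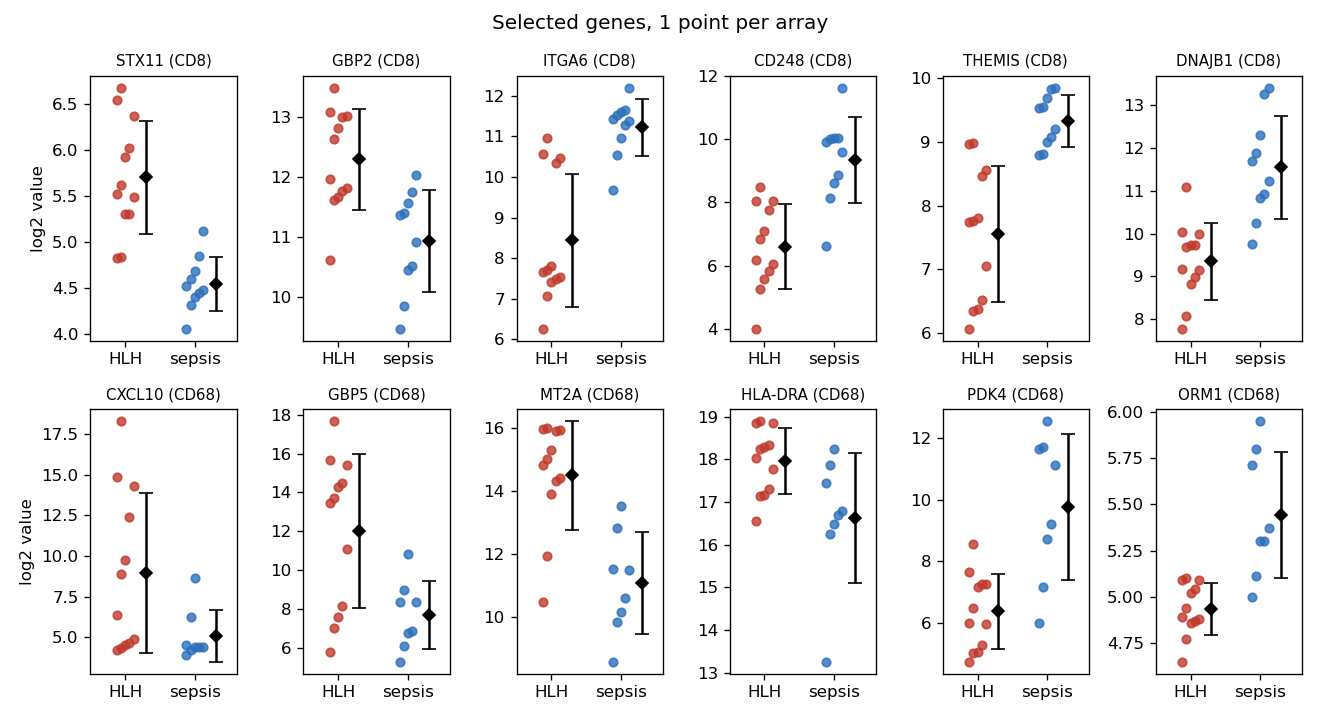
Log2 values of 6 genes in CD8 cells (upper panels) and 6 in CD68 cells (lower panels) per array, HLH in red and sepsis in blue, with the group mean and SD as a diamond with bars; each panel has its own log2 axis. ITGA6, CD248, THEMIS and DNAJB1 were lower and STX11 and GBP2 higher in HLH CD8 cells, while none of the CD68 genes passed the threshold.

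In CD68 monocytes none of the genes in this paragraph passed the threshold. GBP5, an interferon-inducible GTPase, was at 12.03 ± 3.96 (SD, n = 12) in HLH and 7.69 ± 1.77 (SD, n = 8) in sepsis, a difference of 4.34 (SE 1.44, limma adjusted p = 0.509), and GBP2 differed by 2.85 (SE 0.82, adjusted p = 0.440). CXCL10 was at 8.96 ± 4.93 (SD) against 5.11 ± 1.59 (SD), a difference of 3.84 (SE 1.74, adjusted p = 0.671), with 10 of 12 HLH arrays above the sepsis median. Of these, replicates 10, 9 and 7 lay only a little above it, at 4.55, 4.64 and 4.89. HLH values ran from 4.26 to 18.29 and sepsis values from 3.92 to 8.65, so the HLH arrays were not raised alike. CXCL9 was below the filter: it exceeded the array median on 6 of 12 HLH and 0 of 8 sepsis arrays, at 7.15 ± 4.50 (SD) and 4.11 ± 0.23 (SD). The stress and metal-binding protein gene MT2A was at 14.51 ± 1.73 (SD) in HLH and 11.08 ± 1.62 (SD) in sepsis, a difference of 3.43 (SE 0.74, adjusted p = 0.417) with 11 of 12 HLH arrays above the sepsis median.

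No single gene passed in CD68 cells: limma called 0 of 12877 genes, with a smallest adjusted p of 0.417, and 918 genes had an unadjusted p under 0.05 where chance gives 643.9. A fit of all 42 arrays called 54 genes, and 52 with the patient as a replicate block. Those fits pool the spread of both populations, so a gene at background in CD8 cells, such as PDK4, gets a smaller SE than in CD68 cells alone. Beside MT2A, the smallest p values among higher genes were those of MT1JP, a metallothionein pseudogene (2.20, SE 0.47), DUS3L (0.38, SE 0.09), CLEC2B, a lectin-like receptor gene (1.20, SE 0.27), and RPL28 (0.49, SE 0.11). Among lower genes they were those of ABCC3 (-0.32, SE 0.07), ORM1, an acute-phase protein gene (-0.51, SE 0.11), PDK4, a pyruvate dehydrogenase kinase gene (-3.39, SE 0.77), ABCC5 (-0.47, SE 0.12) and SIGLECP3 (-0.41, SE 0.10). IFNG differed by -0.03 (SE 0.15), PRF1 by 0.10 (SE 0.11), CD163 by -0.68 (SE 1.79), or 0.34 with the conflicting array counted as HLH, and HLA-DRA by 1.33 (SE 0.49).

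The IFN-gamma list mean, the measure fixed for the study's question, was higher in HLH CD68 cells by 1.63 (two-sided exact permutation p = 0.0222). It was 0.65 ± 1.77 (SD, n = 12) in HLH, from -1.75 to 4.32, and -0.98 ± 0.67 (SD, n = 8) in sepsis, with 10 of 12 HLH arrays above the sepsis median and 7 above every sepsis array. In CD8 cells the difference was 0.42 (permutation p = 0.0721), from 0.19 ± 0.67 (SD, n = 12) in HLH and -0.23 ± 0.23 (SD, n = 10) in sepsis, with 9 of 12 HLH arrays above the sepsis median. With the conflicting array counted as HLH the CD68 difference was 1.45 (exact permutation p = 0.0520). The disease difference in CD68 exceeded that in CD8 by 1.27 over the 19 patients with both populations (exact permutation p = 0.0116, adjusted p = 0.0516 over 25 lists).

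**Figure D2:**
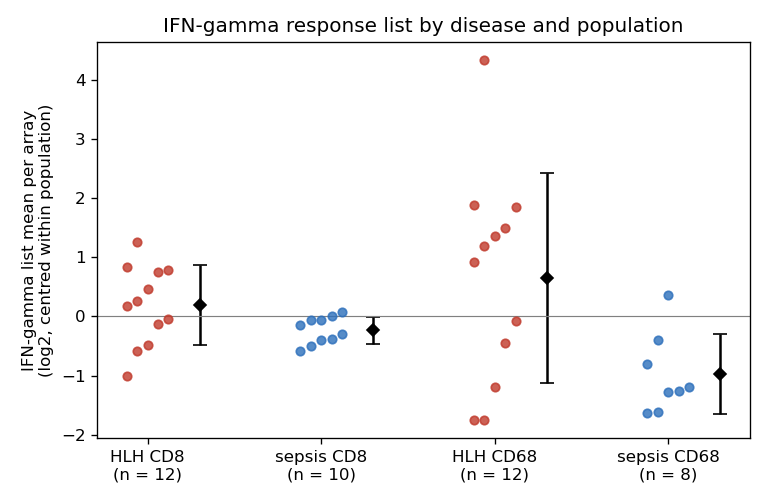
IFN-gamma list mean of each array (log2, centred within its population) by group, HLH in red and sepsis in blue, with the group mean and SD as a diamond with bars. HLH CD68 arrays ran from -1.75 to 4.32, and 7 of the 12 lay above every sepsis CD68 array.

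Camera called 14 of the 26 lists tested in CD68 cells, 9 higher and 5 lower in HLH. No call held with an estimated correlation (lowest adjusted p = 0.379), fry called 0 lists and the permutation tests of the list means called 0, with 4 at an unadjusted p under 0.05. The list of the IFN-gamma response had 28 of 29 genes higher, median 1.24 (adjusted p = 6.82e-12, and adjusted p = 0.379 with an estimated correlation), none past the threshold adjusted over the list alone. WARS1, a tryptophan tRNA synthetase gene induced by IFN-gamma, differed by 3.44 (SE 1.05) and LAP3 by 3.02 (SE 1.0). MHC class I and immunoproteasome genes were higher in 19 of 19, median 0.78 (adjusted p = 2.43e-10, and adjusted p = 0.379 with an estimated correlation), 8 of them past the threshold adjusted over the list alone. CALR differed by 1.79 (SE 0.54), PSME2, a proteasome activator gene, by 2.4 (SE 0.80), PSMB10 by 1.31 (SE 0.42) and TAPBP by 1.03 (SE 0.36). MHC class II presentation genes were higher in 14 of 15, median 1.33 (adjusted p = 1.50e-05, and adjusted p = 0.379 with an estimated correlation). Members included HLA-DRB1 at 1.66 (SE 0.71), HLA-DPA1 at 2.24 (SE 0.96) and RFX5 at 0.57 (SE 0.23). Type I IFN response genes were higher in 28 of 31, median 0.64 (adjusted p = 4.28e-05, and adjusted p = 0.453 with an estimated correlation). EPSTI1 (3.23, SE 0.87) and IFI27 (7.41, SE 2.01) passed adjusted over the list alone, LY6E differed by 1.35 (SE 0.43) and IFI6 by 2.51 (SE 1.22).

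Oxidative phosphorylation genes were higher in 30 of 30 in HLH CD68 cells, median 0.49 (adjusted p = 3.84e-07, and adjusted p = 0.379 with an estimated correlation). Members included CYCS (1.52, SE 0.59), SDHD (1.19, SE 0.44), UQCRQ (0.70, SE 0.31) and UQCRC1 (0.50, SE 0.22). Glycolysis and hypoxia genes were higher in 21 of 24, median 0.20 (adjusted p = 0.00249, and adjusted p = 0.379 with an estimated correlation). TPI1 (1.08, SE 0.26) and PFKP (0.42, SE 0.11) passed adjusted over the list alone, GPI differed by 0.70 (SE 0.27) and HIF1A, the hypoxia factor gene, by 1.11 (SE 0.58). Unfolded protein response genes were higher in 13 of 18, median 0.19 (adjusted p = 0.0239, and adjusted p = 0.379 with an estimated correlation). Members included ATF4 at 1.13 (SE 0.36), HSPA5 at 1.56 (SE 0.60), DNAJC3 at 1.17 (SE 0.44) and EDEM1 at 0.62 (SE 0.29). Immediate early and heat shock genes were higher in 18 of 25, median 0.28 (adjusted p = 0.00855, and adjusted p = 0.453 with an estimated correlation). ZFP36, which destabilises cytokine mRNA, passed adjusted over the list alone at 1.10 (SE 0.29), ATF3 differed by 1.24 (SE 0.42), JUND by 0.87 (SE 0.33) and FOSL1 by 0.46 (SE 0.19). Cytosolic ribosomal protein genes were higher in 21 of 24, median 0.22, which turned to -0.03 after a second quantile normalization (adjusted p = 0.00414, and adjusted p = 0.453 with an estimated correlation). Members included RPS15A at 0.26 (SE 0.09), RPS6 at 0.87 (SE 0.33), RPS16 at 0.74 (SE 0.35) and RPL18 at 0.66 (SE 0.40).

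Lower in HLH CD68 cells was the sepsis monocyte alarmin list, in 18 of 22 genes, median -0.71 (adjusted p = 2.78e-04, and adjusted p = 0.379 with an estimated correlation). VCAN, a monocyte proteoglycan gene, differed by -2.21 (SE 1.0), CSTA by -1.46 (SE 0.54), VNN1 by -1.49 (SE 0.58) and BCL3 by 0.49 (SE 0.14). Monocyte markers were lower in 17 of 21, median -0.68 (adjusted p = 0.00414, and adjusted p = 0.453 with an estimated correlation). Members included TLR4 at -1.49 (SE 0.55), MS4A7 at -1.74 (SE 0.92) and CD68 itself at 0.33 (SE 0.18). Platelet markers were lower in 15 of 15, median -0.96 (adjusted p = 3.84e-07, and adjusted p = 0.379 with an estimated correlation). Members included PPBP at -3.90 (SE 1.70), TUBB1 at -1.84 (SE 0.95), SPARC at -0.81 (SE 0.39) and ITGA2B at -0.96 (SE 0.57). The platelet median was -0.26 without sepsis CD68 replicate 14, the array with the conflicting disease field, and 0.10 with it counted as HLH. T cell markers were lower in 12 of 16, median -0.09 (adjusted p = 0.00855, and adjusted p = 0.453 with an estimated correlation). Members included CD5 at -0.12 (SE 0.06), CD247 at -0.14 (SE 0.08), TRAT1 at -0.19 (SE 0.11) and CD8B at -0.11 (SE 0.07). Neutrophil and granule precursor markers were lower in 8 of 9, median -0.09 (adjusted p = 0.0220, and adjusted p = 0.379 with an estimated correlation). Members included CXCR2 at -0.35 (SE 0.16), CMTM2 at -0.33 (SE 0.19), FCGR3B at -0.93 (SE 0.73) and LCN2 at -0.09 (SE 0.10).

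The other 12 lists tested in CD68 cells were not called. Medians were -0.02 for the cell cycle (adjusted p = 0.258), 0.07 for cytotoxic effector genes (adjusted p = 0.998), -0.02 for T cell activation (adjusted p = 0.440), -0.12 for naive and memory T cell genes (adjusted p = 0.0502) and 0.03 for familial HLH genes (adjusted p = 0.975). They were 0.43 for inflammatory cytokines (adjusted p = 0.103), -0.06 for scavenger and haem handling genes (adjusted p = 0.0832), which include CD163, and -0.06 for the glucocorticoid response (adjusted p = 0.518). The glucocorticoid median turned to 0.33 (adjusted p = 0.0532) without sepsis CD68 replicate 14 and to 0.48 with that array counted as HLH, where camera called the list (adjusted p = 0.0117). For markers of NK cells, B cells, dendritic cells and erythroid cells they were 0.04 (adjusted p = 0.998), 0.0038 (adjusted p = 0.920), -0.04 (adjusted p = 0.518) and -0.10 (adjusted p = 0.129). The median and mean differed in sign for 5 lists, the T cell activation, glucocorticoid, NK cell, B cell and dendritic cell lists, and camera's direction followed the mean for the glucocorticoid, NK cell and B cell lists. Markers of CD4 and regulatory T cells (4 genes, median -0.06), gamma-delta T cells (1 gene, -0.19) and plasma cells (4 genes, median -0.58) were too few to test.

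**Figure D3:**
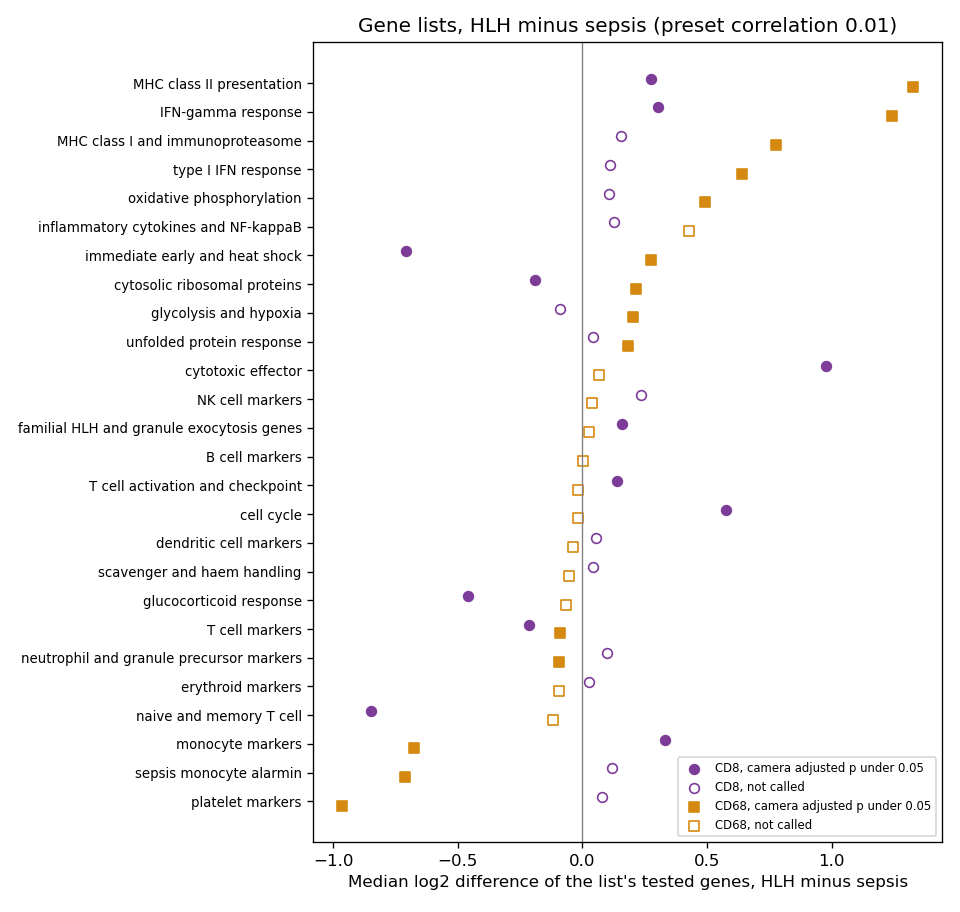
Median log2 difference (HLH minus sepsis) of each gene list in CD8 cells (circles) and CD68 cells (squares), filled where camera's adjusted p was under 0.05 with a preset correlation of 0.01. The IFN-gamma response list lay at 0.30 in CD8 and 1.24 in CD68 cells, and the immediate early and heat shock list at -0.71 and 0.28.

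Whether the populations of a patient moved together was asked with 4 relations between list means. In HLH the IFN-gamma list mean of the CD8 cells rose with that of the CD68 cells over 11 patients (r = 0.919 and rho = 0.936, permutation p = 1.10e-04 for both, adjusted p = 4.40e-04), and r was 0.855 without the 2 patients farthest from the median. In the 8 patients with sepsis r was 0.758 (exact p = 0.0247, adjusted p = 0.0494), rho was 0.690 (exact p = 0.0694, adjusted p = 0.0925) and r was 0.732 without the 2 farthest patients. The sepsis relation was lost with list medians in place of means (r = 0.592, adjusted p = 0.162). For the CD8 cell cycle list mean against the CD68 IFN-gamma list mean in HLH, r was 0.596 (permutation p = 0.0535, adjusted p = 0.0713), rho was 0.900 (permutation p = 3.70e-04, adjusted p = 7.40e-04) and r was 0.829 without the 2 farthest patients. In sepsis this relation had r = 0.0567 (exact p = 0.901, adjusted p = 0.901) and rho = 0 (exact p = 1, adjusted p = 1), and r was 0.812 without the 2 farthest patients. The HLH and sepsis relations were not tested against each other, and no batch is given within which to repeat them.

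**Figure D4:**
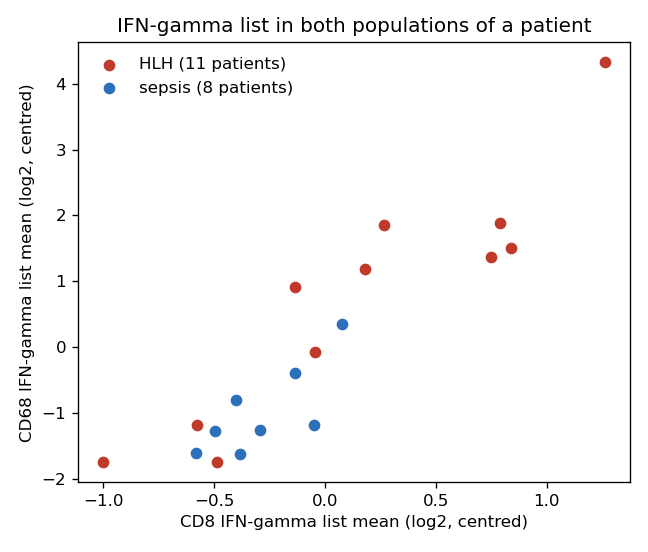
IFN-gamma list mean of the CD8 array (x axis, log2, centred) against that of the CD68 array (y axis, log2, centred) of each of 19 patients, HLH in red and sepsis in blue. The 11 HLH patients had r = 0.919 and the 8 sepsis patients r = 0.758.

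The disease effects in the populations were compared gene by gene. ITGA6, the integrin chain gene, differed by -2.78 in CD8 and 0.04 in CD68 cells (difference 2.82, SE 0.59, limma adjusted p = 0.0202), and THEMIS by -1.78 and 0.03 (difference 1.81, SE 0.38, adjusted p = 0.0218). The differences between the disease effects were 2.80 (SE 0.61) for CD248, 1.90 (SE 0.43) for ETV3, a transcriptional repressor gene, and 1.82 (SE 0.34) for PDE4B, a cyclic AMP phosphodiesterase gene. They were -3.29 (SE 0.74) for PDK4, -2.03 (SE 0.38) for MIR346, -2.01 (SE 0.45) for MIR3910-1, -2.0 (SE 0.36) for MIR483 and -1.83 (SE 0.26) for IGLV5-48. CD248 was at background in CD68 cells (means 4.34 and 4.29) and PDK4 in CD8 cells (4.23 and 4.33), so for both genes the difference restates the effect in the other population. THEMIS is among the T cell markers, all 16 of which were lower in CD68 than in CD8 cells (median -3.59). Its small CD68 effect was thus measured at a lower signal. The CD68 effect of PDK4 did not pass when fitted in CD68 cells alone, and the fit of all arrays pools the spread of both populations. The calls of CD248, ETV3, PDK4 and MIR3910-1 each ended under 1 of 10 alternatives. In all, 48 of 14496 genes passed, 17 with a higher and 31 with a lower effect in CD68 cells, and 88 (35 and 53) with the patient as a replicate block, which included all 48. The count was 27 after a second quantile normalization, 29 with centred arrays, 30 with the filter at the 75th percentile and 73 with array weights. Over the patients with both populations, no list mean passed (lowest adjusted p = 0.0516 over 25 lists, exact permutation).

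The sorted populations carried the mRNA of their lineages. Of 14496 genes, 9082 differed between CD68 and CD8 cells, 3618 higher and 5464 lower in CD68 (limma), and 9320 with the patient as a replicate block. With the arrays centred on their medians the split was 5502 and 4206, where centring moved the median of all genes by 0.15, and without the filter it was 8663 and 5590. LYZ, the lysozyme gene, was higher by 12.50 (SE 0.66), VCAN-AS1 by 12.13 (SE 0.63), the lysosomal thiol reductase gene IFI30 by 11.86 (SE 0.28). CD68 was higher by 9.59 (SE 0.24), the endotoxin co-receptor gene CD14 by 5.19 (SE 0.53) and the growth factor receptor gene CSF1R by 3.90 (SE 0.36). IL7R, the IL-7 receptor gene, was lower by a log2 difference of -8.94 (SE 0.41), and the homing receptor gene CCR7 by -8.67 (SE 0.51). The T cell receptor complex genes were lower too, CD3D by -8.49 (SE 0.26) and CD3E by -5.08 (SE 0.21), and the CD8 genes CD8A by -2.90 (SE 0.19) and CD8B by -3.45 (SE 0.20). LYZ was at the ceiling of the scale in CD68 cells, at 19.87 ± 0.04 (SD, n = 12) in HLH, and CD14 lay below the array medians in CD8 cells, at means of 3.82 in HLH and 3.79 in sepsis. VCAN-AS1 in sepsis CD8 cells (4.32) and CD8B in CD68 cells (4.39 and 4.50) were at background too, so the differences of these 4 genes give the least size they can have.

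All 21 monocyte markers were higher and all 16 T cell markers lower in CD68 cells, with medians of 7.09 and -3.59 (adjusted p = 0.00550 and 0.00572 with an estimated correlation). Marker medians of other cells were 0.34 for neutrophils (adjusted p = 0.00952 with an estimated correlation), 0.35 for dendritic cells (adjusted p = 0.0225 with an estimated correlation). They were 0.64 for platelets (adjusted p = 0.579 with an estimated correlation), 0.59 for erythroid cells (adjusted p = 0.305 with an estimated correlation), 0.40 for B cells (adjusted p = 0.325 with an estimated correlation) and -0.19 for NK cells (adjusted p = 0.726 with an estimated correlation).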

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

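The tests of the immediate early list, of the immunoglobulin lambda genes and of the skin and olfactory families were chosen after their results were seen, and the tests of the IFN-gamma relation and the other splits of the arrays were set before.

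In HLH the IFN-gamma list means of the CD8 and CD68 arrays of a patient moved together (r = 0.919, 11 patients). Monocyte RNA in the CD8 sort would carry the CD68 signal across. Given the CD8 monocyte marker list mean the correlation was 0.903, and that marker mean had r = 0.50 with the CD8 and 0.65 with the CD68 list means. Differences in the amount of monocyte RNA, as this marker mean measures them, thus did not account for the relation. Its genes include CD300E, which lay near the array medians in CD8 cells, so it is an imperfect measure of that amount. A like amount in every patient would still carry each patient's CD68 level across, so carry-over is not excluded. Array contrast would move both lists alike, and given the SDs of both arrays the correlation was 0.933. An interferon exposure shared by both populations of a patient may lie behind the relation, a hypothesis found and tested on the same arrays. Treatment and the time of sampling, which the labels do not give, stay open.

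The immediate early and heat shock list mean was lower in HLH CD8 cells by a difference of -0.79 and differed by 0.28 in CD68 cells. Handling of the blood that acted alike on both sorts would lower both, yet the disease differences of the populations were 1.18 apart over the 19 patients (exact permutation p = 0.0105, adjusted p = 0.0516 over 25 lists). Monocyte RNA diluting the CD8 sort would make the difference shrink with the monocyte marker covariate, and 124% of it was left (-0.99, SE 0.26). A difference in CD8 cell activation may account for it, and so may handling of the CD8 sort alone or treatment, none of which was tested.

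The immunoglobulin lambda variable genes were higher in HLH CD8 cells in 14 of 14, with a median of 0.44, and 7 passed the threshold. The heavy chain (IGHV) and kappa (IGKV) variable genes had medians of 0.04 (12 of 19 higher, permutation adjusted p = 0.0259, and adjusted p = 0.382 with an estimated correlation) and 0.16 (18 of 23 higher, permutation adjusted p = 0.0689, and adjusted p = 0.272 with an estimated correlation). RNA from B or plasma cells would bring their other transcripts, and the 6 tested markers of these cells that no other list holds had a median of -0.037 (SD 0.18, from -0.32 to 0.18), with IGHA1 at 4.66 in HLH and 4.75 in sepsis and CD79A at 5.19 and 5.24 (a set narrowed after wider sets had been seen, with the same outcome). IGHM, which is in neither marker list, was at 4.85 and 5.12. A raised background of the arrays was predicted to end the calls once it was adjusted for. With the mean of the skin and olfactory families as a covariate 100% of the 7 calls stayed past the threshold (median 1.28 before and 1.10 after, highest adjusted p = 0.0434). That mean differed by 0.09 between the groups, which is small beside 1.28, so the covariate could take away little. A background particular to these probe sets is not excluded. Transcription of these loci in CD8 cells, or cross-hybridization of their probe sets, may account for the pattern, and neither was tested.

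In the keratin-associated, late cornified envelope, SPRR and olfactory receptor families 14 genes passed the threshold in CD8 cells, and 12 of them still did with the mean of these families as a covariate. The keratin-associated genes were higher in 34 of 41 (permutation adjusted p = 0.0120, and adjusted p = 0.157 with an estimated correlation) and the late cornified envelope genes in 10 of 13 (permutation adjusted p = 0.0123, and adjusted p = 0.207 with an estimated correlation), while the olfactory receptor genes were higher in 37 of 59 (permutation adjusted p = 0.279). A background difference cannot be told apart from a real one for these families, since the covariate was made from them and the mean of its genes differed by 0.09 (4.17 ± 0.12 SD in HLH, n = 12, and 4.08 ± 0.14 SD in sepsis, n = 10, permutation p = 0.109). No biological explanation was tested for them.

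Splits of the arrays into other groups of the same sizes were drawn, 100 for each result with the real one included. The real split alone, 1 of 100, reached the count of 346 genes in CD8 cells (highest other split 2) and of 48 genes whose disease effects differed (highest other 5). It alone also reached the 9082 genes between CD68 and CD8 cells (highest other 6530, with the populations swapped within patients). Chance alone is thus an unlikely source of these counts as a whole. The splits do not exclude chance for single genes among them, nor a batch or treatment that follows the disease groups. For CD68 genes the splits decide nothing, since all 100 reach a real count of 0 by construction (limma, 918 at an unadjusted p under 0.05; highest other 55). For the lists called by camera in CD8 cells chance could not be excluded (12 called, 17 splits as high, highest other 17, median of the others 8). For those in CD68 cells few splits were as high (14 called, 3 splits as high, highest other 14, median of the others 7). Other splits tied the real count, and no call held with an estimated correlation, by fry or by permutation. The count therefore does not exclude chance for any of these lists.

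A sample stood apart from the rest of its sepsis group in 23 of 186 series of values (11 in sepsis CD8 and 12 in sepsis CD68), while chance gives about 1 in 20 groups. The test was run in the sepsis groups only, so samples standing apart within the HLH groups were not looked for. The values below are the gap to the nearest sample divided by the range of the group. In sepsis CD8, replicate 22 was highest for the dendritic cell marker list mean (0.525; 0.19 against -0.14 to 0.02), IGLV5-48 (0.550; 5.98 against 4.07 to 4.93), IGLV11-55 (0.541; 6.41 against 4.47 to 5.36) and IGHV2-70 (0.632; 5.50 against 4.36 to 4.78). Replicate 17 was highest for the platelet list mean (0.654; 1.33 against -0.40 to 0.20), replicate 16 for PRF1 (0.564; 11.41 against at most 8.66) and LYZ (0.573; 9.08 against at most 6.69), replicate 14 for NUSAP1 (0.471) and HAVCR2 (0.565), and replicate 19 for CD300E (0.513). Replicate 21 was lowest for BCL11B (0.512; 7.06 against at least 9.03).

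In sepsis CD68, replicate 16 was highest for the type I IFN list mean (0.792; 2.50 against -1.32 to -0.53), LAP3 (0.543), LY6E (0.671) and IFI6 (0.628; 13.35 against at most 8.30). Replicate 14, whose disease field conflicts with its title, was highest for the platelet genes SPARC (0.618), TUBB1 (0.569; 14.44 against at most 8.60) and ITGA2B (0.699; 10.64 against at most 6.4). Replicate 20 was lowest for DUS3L (0.593) and GPI (0.532) and highest for CMTM2 (0.554), replicate 15 was lowest for HLA-DRA (0.60; 13.26 against at least 16.25) and replicate 21 for RPS16 (0.628; 15.16 against at least 17.49).

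The disease effect differed between CD68 and CD8 cells for 14 of the named genes (limma adjusted p from 1.60e-04 to 0.0318). Among the immunoglobulin lambda genes the CD68 effect minus the CD8 effect was -1.83 for IGLV5-48, -1.63 for IGLV4-60 and -1.31 for IGLV11-55. Among the microRNA genes it was -2.0 for MIR483, -2.03 for MIR346 and -2.01 for MIR3910-1. For genes lower in HLH CD8 cells it was 2.82 for ITGA6, 2.80 for CD248, 1.82 for PDE4B, 1.81 for THEMIS, 1.73 for SNAPC1 and 1.90 for ETV3. It was also -0.38 for ABCC3 and -3.29 for PDK4. CD248 did not pass the low-signal filter in CD68 cells, nor ABCC3 and PDK4 in CD8 cells, so for these 3 genes the value restates the effect in the other population. THEMIS, a T cell marker, had a lower signal in CD68 than in CD8 cells. The CD68 effects of ABCC3 and PDK4 did not pass when fitted in CD68 cells alone.

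Probe sets without a single gene symbol were not used in the comparisons. Those with autosomal identifiers were tested apart, with the same low-signal filter. In CD8 cells 1119 of 18242 of them passed the threshold between HLH and sepsis, 578 higher and 541 lower (4036 at an unadjusted p under 0.05, where chance gives 912.1). In CD68 cells limma called 0 of 19243, with 1093 at an unadjusted p under 0.05.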

How the results depend on the processing

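The alternatives without low-weight arrays, with the background families and with the array SD as covariates, and the permutation tests of all lists were chosen after seeing the data, as was reading a list's direction from the sign of its median. Unless construction is named, the cause was not tested.

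In CD8 cells the 346 genes became 123 with the 75th percentile filter and 81 with a log2 difference of at least 1, both of which admit fewer genes by construction. They became 131 with the other sort's markers as a covariate (117 of them shared), 657 with the background families and 580 with the array SD as covariates. Under the other 9 alternatives the count lay between 236 and 454. The 12 lists called became 6 with the other sort's markers as a covariate, 0 with an estimated correlation, 1 by fry and 2 by permutation.

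In CD68 cells the 0 genes of limma (918 at an unadjusted p under 0.05) became 54 in 1 fit of 42 arrays and 52 with the patient as a replicate block, and stayed 0 otherwise. The 14 lists called became 0 with an estimated correlation, 0 by fry and 0 by permutation.

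The 48 genes whose disease effects differed became 30 with the 75th percentile filter, 27 quantile normalized again, 29 with centred arrays, 73 with array weights, 88 with the replicate block and 28 with a log2 difference of at least 1. The 9082 genes between CD68 and CD8 cells became 14253 without the filter (8663 higher and 5590 lower in CD68), 5842 with the 75th percentile filter and 2870 with a log2 difference of at least 1.

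The IFN-gamma list mean difference in CD8 cells was 0.29 with medians over genes (permutation p = 0.0492) and 0.41 without low-weight arrays (HLH CD8 replicates 4 and 10 and sepsis CD8 replicate 21, permutation p = 0.0449), where 0.42 had p = 0.0721. In CD68 cells it was 1.45 with the conflicting array as HLH (exact p = 0.0520). The sepsis relation of the IFN-gamma list means was 0.592 with medians over genes.

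Directions turned as follows. With the other sort's markers as a covariate in CD8 cells: CD163 -0.10, and the lists scavenger -0.033, alarmin -0.016, oxidative phosphorylation -0.012, unfolded protein response -0.0011, monocyte markers -0.016, dendritic cells -0.015 and erythroid cells -0.023; in CD68 cells IFNG 0.037. With the conflicting array as HLH in CD68 cells: IFNG 0.0032, CD163 0.34, ITGA2B 0.19, and the lists naive and memory T cell 0.0038, scavenger 0.036, glucocorticoid 0.48 (called, adjusted p = 0.0117) and platelet 0.10. With that array left out: scavenger 0.00030 and glucocorticoid 0.33. Without the filter in CD68 cells: cell cycle 0.0017, T cell activation 0.0096 and B cells -0.027. With the 75th percentile filter: T cell activation 0.14. Quantile normalized again: T cell activation 0.0023, familial HLH genes -0.018 and ribosomal proteins -0.032. With centred arrays: B cells -0.013. Without low-weight arrays: glucocorticoid 0.0081 and B cells -0.013.

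Of the values of single genes under alternatives, 595 in CD8 and 855 in CD68 cells kept direction and side of the threshold, 44 in CD8 cells lost their call and 44 in CD8 and 21 in CD68 cells gained one. The calls of APOL6 and KLF9 in CD8 cells ended under 8 and 9 of 11 alternatives (adjusted p up to 0.201 and 0.126). Calls were gained in CD8 cells by SATB1 (6 of 11 alternatives), CXCR6 (5 of 10), CD3E (4 of 11), LRRN3 and BCL11B (3 of 11 each), by HLA-DRA, SERPING1, MKI67, CENPF, GZMB, FASLG, LAG3, LEF1, ERRFI1 and CD3G (2 each) and by HLA-DOA, SGK1 and RPL10A (1 each). In CD68 cells MT1JP, MT2A, ABCC3, PDK4, ABCC5, GBP2, WARS1, LAP3, EPSTI1 and IFI27 gained one in the fits of 42 arrays without and with the replicate block (52 genes called with it), and SIGLECP3 in 1 of them. Of those of lists, 281 in CD8 and 326 in CD68 cells kept both, 54 and 57 lost their call and 2 and 9 gained one. These counts leave out the 7 and 16 values whose direction turned. Among the turned values the CD8 monocyte marker, CD68 platelet and CD68 ribosomal lists also lost a call. The CD68 glucocorticoid list gained one there. In CD8 cells 14 alternatives ended the calls of the T cell activation list 9 times, MHC class II and familial HLH 8, IFN-gamma 6, cell cycle and cytotoxic 4, naive and memory, ribosomal, T cell marker and monocyte marker 3, immediate early 2 and glucocorticoid 1. Beyond these 3, the monocyte marker call also ended with the covariate made from that list, where its median turned (camera adjusted p = 0.944). In CD68 cells 16 alternatives ended those of the immediate early list 7 times, unfolded protein response and ribosomal 5, and glycolysis and monocyte marker 4. Beyond these 5, the ribosomal call also ended after a second quantile normalization, where its median turned (camera adjusted p = 0.805). Of 15 alternatives, 6 ended the T cell marker call and 5 the neutrophil call. The other 7 CD68 lists lost theirs 3 times, with an estimated correlation, by fry and by permutation. The platelet call also ended with the conflicting array counted as HLH, where its median turned (camera adjusted p = 0.803). Signal over background was limited for genes near the array median and at the ceiling of the scale.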

Other observations

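The gene families below were chosen after the data were seen, and the 3 relations at the end were set before their results.

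Metallothionein genes were higher in HLH CD68 cells in 13 of 13, with a median of 2.17, and 13 passed when adjusted over the family alone. Camera's adjusted p was 3.04e-17, and 0.0932 with an estimated correlation, and the permutation test of the family mean gave an adjusted p of 0.0138. MT1F differed by 3.67, MT1G by 2.94 and MT1X by 2.31. In CD8 cells 12 of 12 were higher with a median of 0.40 (permutation p = 0.177). Proteasome genes outside the MHC class I list were higher in HLH CD8 cells in 30 of 31, median 0.40 (permutation adjusted p = 0.0259, and 0.207 by camera with an estimated correlation), with PSMA3 at 1.19, and in CD68 cells in 28 of 31, median 0.29 (permutation adjusted p = 0.836). T cell receptor alpha variable genes were lower in HLH CD8 cells in 16 of 18, median -0.62 (permutation adjusted p = 0.0259, and 0.207 by camera with an estimated correlation), with TRAV14DV4 at -1.39. The beta variable genes were lower in 23 of 33, median -0.18 (permutation adjusted p = 0.238, and 0.382 by camera with an estimated correlation). Histone genes were higher in 30 of 32 in CD8 cells, median 0.63 (permutation adjusted p = 0.191), and in 26 of 31 in CD68 cells, median 0.48 (permutation adjusted p = 0.204). None of these directions turned with quantile normalized or centred arrays, although the proteasome median in CD68 cells was 0.14 after a second quantile normalization.

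If the CD8 cells were a source of IFN-gamma acting on the monocytes, the CD8 level of IFNG would rise with the CD68 IFN-gamma list mean. Over 11 HLH patients rho was 0.864 (permutation p = 0.00109, adjusted p = 0.00163) and r was 0.701 (permutation p = 0.0158, adjusted p = 0.0237), or 0.776 without the 2 farthest patients. This may reflect such a source, and another factor acting on both populations gives the same relation.

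If proliferating CD8 cells were effector cells, the cell cycle and cytotoxic list means would move together. Over 12 HLH CD8 arrays rho was 0.923 (permutation p = 6.00e-05, adjusted p = 1.80e-04) and r was 0.792 (permutation p = 0.00108, adjusted p = 0.00324), or 0.813 without the 2 farthest arrays. Arrays of whole sorted populations cannot tell whether the same cells carried both programs, and another factor acting on both gives the same relation. If the metallothionein difference belonged to the interferon response, both would move together in CD68 cells. Over 12 HLH CD68 arrays rho was 0.762 (permutation p = 0.00554, adjusted p = 0.00554) and r was 0.579 (permutation p = 0.0491), or 0.563 without the 2 farthest arrays. Here too another factor acting on both lists gives the same relation.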
